A study of Homo sapiens with 23 samples.

How the data were processed

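Total RNA of MCF10A WT and ErbB2* cells in 2D and 3D culture was measured on 23 single-colour Illumina bead arrays, 1 array per sample. RNA was extracted on RNeasy columns and labelled with biotin through the Illumina TotalPrep amplification kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. One sample carried conflicting labels: its title, source and description placed it with WT cells in 3D (replicate 5), while its cell line field named ErbB2*. It was kept with WT cells in 3D. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

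The authors deposited 2 kinds of values. The scanner table held the average bead intensity of each probe on each array, per the file headers, on a linear scale and not normalised between arrays. Beside each intensity the authors deposited a detection p-value, per the file headers, which sets the probe against the negative controls of its array. The software, its version and any earlier correction are not given in the sources used here. The second table held values that the authors had normalised between arrays, with no stated scale. Set against each array's own scanner signals above 1000, these deposited values had slopes between 0.948 and 1.02 per log2 unit on 22 arrays, so they were read as log2 values. They ranged from 7.15 to 15.2, with array medians between 7.42 and 7.43, and the normalisation method is not given in the sources used here. With that range, the values were not centred by gene. In WT 3D replicate 5 the slope was 0.671 and the rank correlation of the deposited log2 column with its own scanner column was 0.503, against 1.000 on the other arrays. No per-sample column was left unused.

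The analysis started from the scanner intensities. Background was corrected with the normexp model, its negative-control moments inferred from the detection p-values, an offset of 16 was added, and the arrays were quantile normalised and taken to log2 (neqc of limma 3.58.1 in R 4.3.3, with version 1.17.8 of the package data.table to read the values). Probes were named through the platform annotation that pairs probes with gene symbols. Of 48803 probes 28098 had 1 gene symbol, 13 had several and 20692 had none listed; 28059 matched a current gene through their Entrez ID and no symbol needed an update. A probe was kept if its detection p was under 0.05 on at least 5 arrays, which left 17689 probes, 14612 of them with 1 symbol. Each gene was represented by its brightest probe over all arrays, and 10954 genes were tested; 2886 of them had more than 1 passing probe, and the report says where probes of a named gene disagreed. A gene's probe below background (detection p of 0.05 or more) on every array of a group, or, by a limit set after seeing the data, on more than 1/2 of them, has only a bound there, and its fold is given as at least the ratio of the brighter group's mean to the mean of the higher of its own signal and the lowest detected signal per array. Array signal over background sets which genes can be measured: 9329 probes were detected on WT 3D replicate 5 and at least 15080 on each other array.

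A means model of the 4 groups was fitted to all 23 arrays with limma (lmFit, contrasts.fit and eBayes, 19 residual degrees of freedom). The 5 comparisons were ErbB2* against WT in 2D, the same in 3D, 3D against 2D in WT cells, 3D against 2D in ErbB2* cells, and the interaction of cell line and culture. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes of a comparison, the threshold was 0.05, and a further count took absolute log2 changes of at least 1. Adjusted p-values in the report come from limma. Gene lists of pathways, cell states and other cell types were fixed before the data were examined, 33 in all; 32 had at least 5 tested members. They were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over 160 tests, and again with an estimated correlation. Counts of members that rose or fell are given over all genes and adjusted over the list alone. Of the list results in the report, those that lost their call with an estimated correlation have that p printed beside them. The named genes were also chosen by a rule fixed before the data were examined. They were ERBB2, the 5 highest and 5 lowest changes among called genes whose 2 groups did not overlap on any array, and the 3 largest changes past the threshold in each of the 8 lists with the smallest camera p. For the interaction they were the 5 highest and 5 lowest differences. In a random order, 6 and 6 arrays do not overlap in 0.216% of genes and 6 and 5 arrays in 0.433%.

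The alternatives set before the data were examined were no background correction, normexp with an offset of 50 on the signals alone, median scaling, the deposited log2 values, no detection filter, a stricter one (p under 0.01 on at least 11 arrays), the mean over a gene's probes, only the groups compared in the fit, a trended and robust eBayes, array weights, the replicate number as a block, and leaving out each array in turn. Slide was planned as a block but was not run, because no slide is given in the sources used here. Runs on the 22 arrays other than WT 3D replicate 5, with the normalisation repeated or with the deposited values, were added after seeing the data. Median scaling moved the median log2 change of all genes from 0.01 to 0.20 (ErbB2* against WT, 2D), from 0.04 to 0.40 (3D), from -0.06 to -0.34 (3D against 2D, WT), from -0.02 to -0.14 (ErbB2*) and from 0.02 to 0.19 (interaction), so up and down counts are relative to the scaling.

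The fit was tested on simulated data of 10954 genes, where 67, 67 and 66 genes per comparison had log2 changes of 0.5, 1 and 2. It recovered 41.8%, 77.6% and 98.5% for ErbB2* against WT in 2D, 34.3%, 77.6% and 95.5% in 3D, 22.4%, 70.2% and 97.0% for culture in WT cells, 20.9%, 67.2% and 98.5% in ErbB2* cells, and 14.9%, 44.8% and 92.4% for the interaction. The share of false calls lay between 4.22% and 6.29%. The simulated noise was independent between genes and had the same spread on every array. It held no outlying array and no sets of arrays within a group, so these shares need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3 in Python 3.11.15. Transcripts of the engineered construct and gene positions were not analysed here.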

Results

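RNA from MCF10A cells was profiled on 23 Illumina bead arrays that carry 48803 probes. MCF10A is an immortalised, non-tumorigenic human mammary epithelial cell line. The unmodified cells (WT) were set beside an ErbB2-engineered derivative that the labels call MCF10A/ErbB2* (here ErbB2*), and both were grown in 2D and in 3D culture. ERBB2 encodes a receptor tyrosine kinase of the epidermal growth factor receptor family. The labels do not describe the ErbB2* construct or the 3D culture medium. There were 6 arrays of WT cells in 2D, 5 of WT cells in 3D, 6 of ErbB2* cells in 2D and 6 of ErbB2* cells in 3D. The number of arrays limits the precision of every value. On 22 of the arrays the mean probe signal lay between 333.6 and 581.6 units, and 30.9% to 34.6% of the probes were detected above background. Replicate 5 of WT cells in 3D stood apart, with a mean signal of 150.6 and 19.1% of its probes detected. It was kept in its labelled group, and counts without it are given beside each comparison. In a principal component analysis of the other 22 arrays, the first component held 31.5% of the variance and the second 22.4%, and the arrays lay in 4 clusters that matched the labelled groups.

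**Figure D1:**
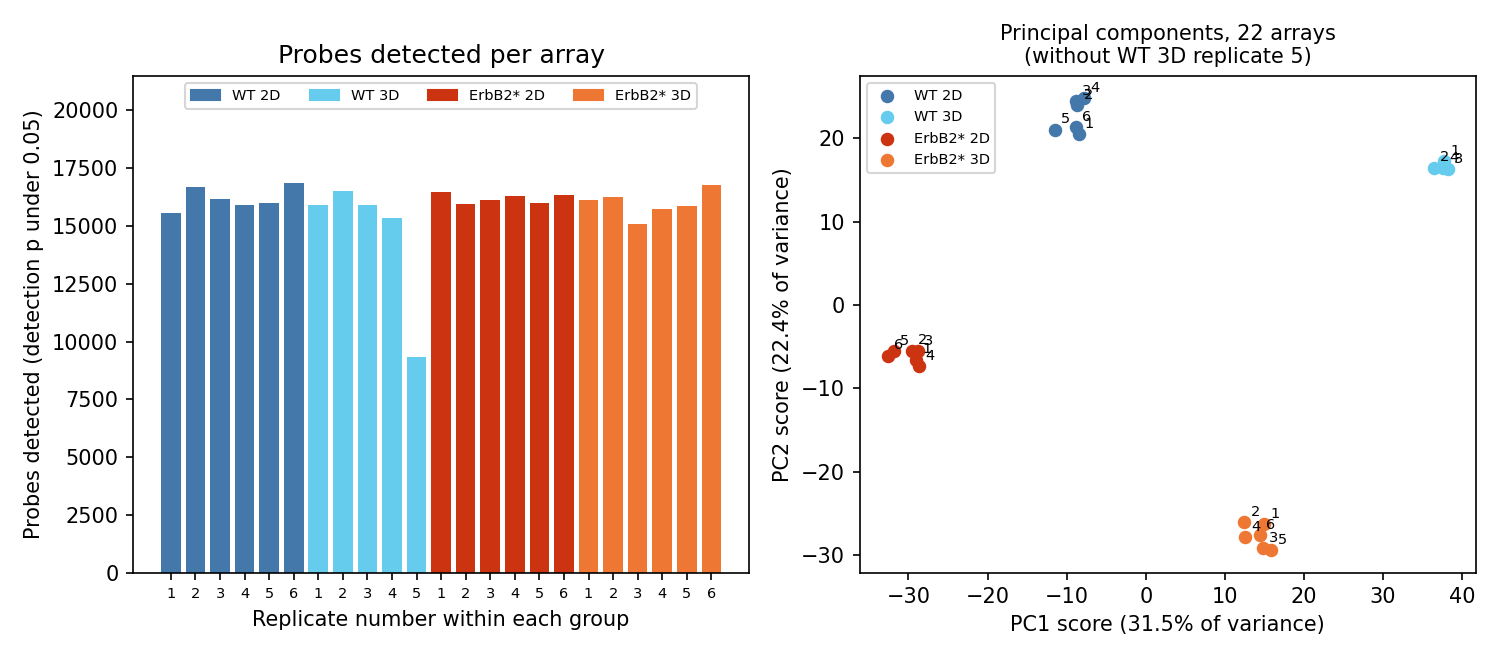
Left, number of probes detected above background on each of the 23 arrays, coloured by group, with replicate numbers on the horizontal axis; WT 3D replicate 5 has 9329 detected probes. Right, scores of the 22 other arrays on the first component (31.5% of variance, horizontal) and the second (22.4%, vertical), where the 4 labelled groups form 4 clusters.

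The engineered gene was examined first. Of 3 ERBB2 probes, 1 was detected on every array, and its normalised log2 signal was 8.68 ± 0.136 (SD, n = 6) in WT cells in 2D, 8.36 ± 0.225 (SD, n = 5) in WT cells in 3D, 8.67 ± 0.118 (SD, n = 6) in ErbB2* cells in 2D and 8.04 ± 0.252 (SD, n = 6) in ErbB2* cells in 3D. No difference between ErbB2* and WT cells passed the test in 2D (log2 difference -0.0044, SE 0.117, adjusted p = 0.991). In 3D the difference was -0.32 (SE 0.123, adjusted p = 0.0608). This value passed the threshold when WT 3D replicate 4 (-0.38), WT 3D replicate 5 (-0.34), ErbB2* 3D replicate 2 (-0.39) or ErbB2* 3D replicate 5 (-0.37) was left out. Between 3D and 2D culture ERBB2 differed by -0.32 in WT cells (adjusted p = 0.0537). That value passed without WT 2D replicate 3 (-0.35), WT 3D replicate 3 (-0.41), ErbB2* 3D replicate 2 (-0.32) or ErbB2* 3D replicate 6 (-0.32), and under some processing alternatives given below. In ErbB2* cells ERBB2 fell by 0.64 from 2D to 3D (SE 0.117, adjusted p = 2.6e-04), a call that was lost under median scaling (log2 change -0.81, adjusted p = 0.134). Whether the probe lies within the engineered sequence is not given in the sources used here, so this level checks neither the label nor the transgene.

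ErbB2* and WT cells were first compared in 2D culture, to show which transcripts differed between the cell lines when grown flat. The design holds no other ErbB2* or WT line. Effects of the engineered gene therefore cannot be told apart from other differences between the lines. The gene with the highest fitted change was FGL1, which encodes a secreted fibrinogen-like protein. Its log2 signal was 9.63 ± 0.177 (SD, n = 6) in ErbB2* cells, at least 22.2-fold above WT cells, where its probe was below background on every array. IL1RL1, the receptor for interleukin 33, and CD74, the invariant chain of MHC class II, were below background on most WT 2D arrays and at least 20.4-fold and at least 14.2-fold higher in ErbB2* cells. SERPINB3 and SERPINB4, protease inhibitors of squamous epithelia, were below background on every WT 2D array and at least 15.2-fold and at least 12.3-fold higher in ErbB2* cells. The lowest gene was SCG5, a secretory granule chaperone, with a log2 change of -4.00 (SE 0.191, adjusted p = 3.05e-13).

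KRT14, the keratin of basal epithelial cells, followed with a log2 change of -2.86 (SE 0.136). PMEPA1, a target of TGF-beta signalling, changed by -2.85, EVA1A by -2.76 and C1orf116 by -2.70. These 10 genes were chosen so that every ErbB2* array lay beyond every WT array, and their adjusted p was at most 2.01e-09. Another FGL1 probe gave -0.15 and another SERPINB3 probe gave 1.22, so the size depended on the probe. SERPINB3 and SERPINB4 are near-identical in sequence, so their probes cannot be assumed to tell them apart and the 2 values are uncertain.

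Interferon response genes and antigen presentation genes rose together in ErbB2* cells in 2D. Of 37 tested interferon genes 25 rose and none fell (28 rose when adjusted over the list alone), with a median log2 change of 1.03 (adjusted p = 1.04e-22). Examples were IFI27 (log2 change 2.48), the transcription factor IRF1 (2.31) and the oligoadenylate synthetase OAS2, whose probe was below background on every WT 2D array and which was at least 3.92-fold higher. The log2 signal of IRF1 in WT 2D cells was 8.13 to 8.37 in replicates 1, 5 and 6. It was 6.01 to 7.05 in replicates 2, 3 and 4, so the size of its change depended on the WT arrays. Of 15 antigen presentation genes 11 rose and none fell (13 over the list alone; median 1.39, adjusted p = 1.21e-18). Besides CD74, HLA-DRA was at least 10.3-fold higher and HLA-DPA1 at least 5.85-fold, both below background on most or all WT arrays in 2D. Leukocyte markers, a list for another cell type, moved with these groups. Of its 8 tested members 4 rose and 1 fell (median 0.36, adjusted p = 0.0299; adjusted p = 0.0873 with an estimated correlation and 0.0657 under median scaling). Of 27 NF-kB and cytokine genes 13 rose and none fell (14 rose and 1 fell over the list alone; median 0.39, adjusted p = 7.51e-09). The acute-phase gene SAA1 rose by 2.60 and the cytokine IL6 by 1.81, while SAA2 was at least 4.23-fold higher than its below-background level in WT cells. SAA1 and SAA2 are near-identical in sequence, and their separate values are uncertain.

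Of 20 NRF2 targets, genes of the antioxidant and detoxification response, 9 rose and none fell (9 over the list alone; median 0.27, adjusted p = 1.2e-08). AKR1B10 rose by 2.13, the transporter ABCC2 by 1.95 and AKR1C3 by 1.16. Of 5 adipocyte markers 3 rose (3 over the list alone; median 0.84, adjusted p = 1.36e-05).

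Basal markers, YAP and TEAD targets and TGF-beta targets fell in ErbB2* cells in 2D. Of 13 basal and myoepithelial markers 9 fell and 1 rose (10 fell and 1 rose over the list alone; median -1.003, adjusted p = 3.95e-09). Besides KRT14, the actin-binding protein gene TAGLN fell by 2.00 and the laminin gene LAMB3 by 1.74, although other LAMB3 probes gave -0.39 and -0.33. Of 19 YAP and TEAD targets 7 fell and none rose (9 fell over the list alone; median -0.54, adjusted p = 3.86e-08), among them CCN1 (-2.04), F3 (-1.51) and CCN2 (-1.501). Of 20 TGF-beta targets 10 fell and 1 rose (12 fell and 2 rose over the list alone; median -0.74, adjusted p = 5.6e-07), among them PMEPA1, TAGLN and THBS1, the gene of thrombospondin 1 (-2.67). Fibroblast markers moved the same way, with 4 of 8 lower and 1 higher (median -0.50, adjusted p = 0.0391, and adjusted p = 0.147 with an estimated correlation).

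Of 20 epithelial junction and polarity genes 6 fell and none rose (7 fell over the list alone; median -0.57, adjusted p = 1.62e-06). This call was lost with an estimated correlation (adjusted p = 0.167). CDH3, the gene of P-cadherin, fell by 1.46, the tight junction gene CLDN1 by 1.36 and the polarity gene CRB3 by 1.22. Under median scaling CDH3 (-1.21, adjusted p = 0.0558) and CRB3 (-1.06, adjusted p = 0.0586) did not pass. The 6 WT arrays in 2D fell into 2 sets of 3, and the median of this list differed by 0.30 between them.

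In all, 1436 of 10954 tested genes differed between ErbB2* and WT cells in 2D, 852 higher and 584 lower in ErbB2* cells, and 421 of them by at least 2-fold. Without WT 3D replicate 5, an array outside this comparison that shares the estimate of spread, 2543 genes passed, including all 1436. Median scaling in place of quantile normalisation moved the split to 483 higher and 151 lower genes.

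**Figure D2:**
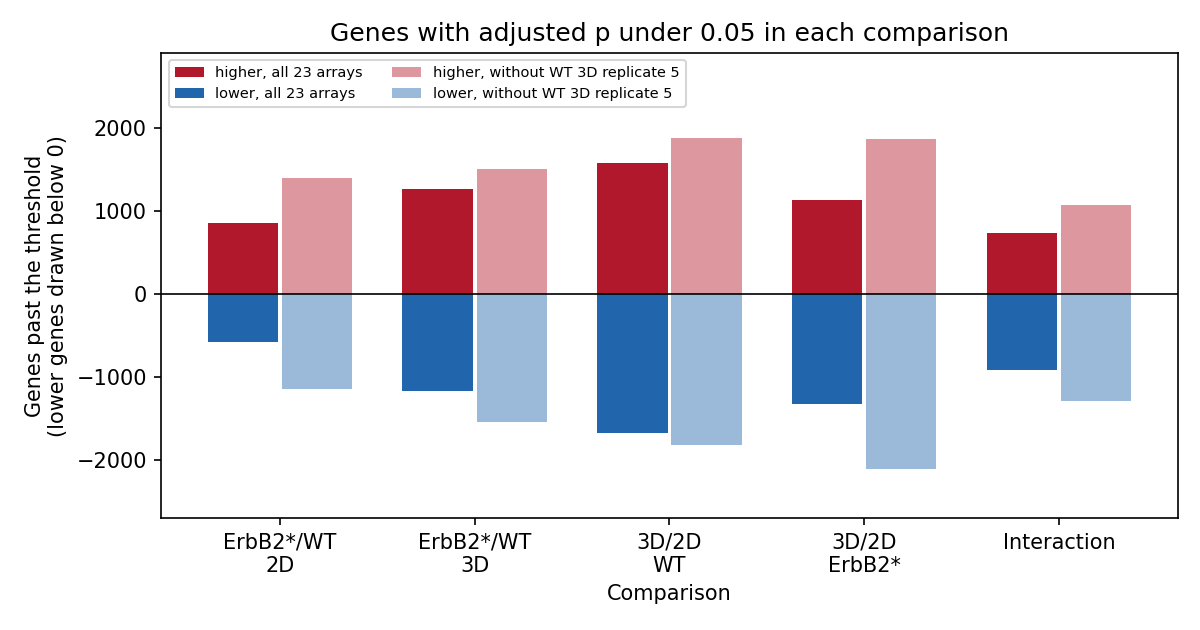
Number of genes past the adjusted p threshold in each comparison (vertical axis, higher genes above 0 and lower genes below 0), with all 23 arrays in dark colours and without WT 3D replicate 5 in light colours. In the 2D comparison of ErbB2* with WT cells the count went from 1436 to 2543.

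The same comparison was made in 3D culture. SRGN, the core protein of secretory granule proteoglycans, was higher by a log2 change of 5.32 (log2 signal 11.9 ± 0.143, SD, n = 6, against 6.62 ± 0.982, SD, n = 5). FABP4, a fatty acid binding protein of adipocytes and macrophages, was at least 25.7-fold higher and the chemokine gene CXCL2 at least 16.9-fold, both below background on most WT 3D arrays. The probes that stand for IL6 and for the lipid droplet gene CIDEC were below background on every WT 3D array and at least 17.6-fold and at least 14.6-fold higher in ErbB2* cells. Another CIDEC probe was detected on 2 of the WT 3D arrays and gave a log2 change of 1.10.

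The lowest gene was the basal keratin gene KRT15, at a log2 change of -3.95 (SE 0.202, adjusted p = 7.35e-13). DLK2 and SRGAP3 were each lower by a log2 change of -3.67, P3H2, a collagen prolyl hydroxylase gene, by -3.65 and LAD1, the gene of the basement membrane-associated protein ladinin, by -3.54. The other SRGAP3 probes ranged from -1.95 to -0.04. By the rule that chose these 10 genes, every ErbB2* array lay beyond every WT array.

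Of 27 NF-kB and cytokine genes 23 rose and 2 fell (the same numbers over the list alone; median 1.22, adjusted p = 1.17e-17). CSF3, the gene of granulocyte colony-stimulating factor, was at least 13.1-fold higher beside IL6 and CXCL2. Of 37 interferon response genes 26 rose and none fell (27 rose and 1 fell over the list alone; median 0.91, adjusted p = 1.63e-13), among them IRF1 (log2 change 2.48). IFI27 and the immunoproteasome gene PSMB9, like CSF3 below background on most WT 3D arrays, were at least 7.87-fold and at least 3.07-fold higher. Of 15 antigen presentation genes 12 rose and none fell (13 rose over the list alone; median 1.14, adjusted p = 1.82e-13). HLA-DRA, HLA-DPA1 and HLA-DMB were below background in WT cells in 3D and at least 8.12-fold, 7.17-fold and 3.07-fold higher in ErbB2* cells. Of 8 leukocyte markers 3 rose and 1 fell (median 0.09, adjusted p = 0.387).

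Of 21 genes transcribed downstream of ERK signalling 13 rose and none fell (13 rose and 1 fell over the list alone; median 0.88, adjusted p = 2.23e-08), among them IER3 (log2 change 3.43), the feedback inhibitor SPRY4 (2.25) and the ephrin receptor EPHA2 (2.23). Of 5 adipocyte markers 3 rose (4 over the list alone; median 2.23, adjusted p = 2.84e-07): FABP4, CIDEC and PPARG, the adipogenic nuclear receptor gene (2.23). Of 20 NRF2 targets 10 rose and 1 fell (the same over the list alone; median 0.40, adjusted p = 7.0e-06), among them HMOX1 (1.76), the ferritin light chain gene FTL (1.76) and TXNRD1 (1.73). WT 3D replicate 5 decided the size for FTL, which rose by 0.89 without it, and FTL did not pass under median scaling (2.29, adjusted p = 0.0614) or with only the groups compared in the fit (1.76, adjusted p = 0.131).

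Of 20 epithelial junction and polarity genes 8 fell and none rose (8 fell and 1 rose over the list alone; median -0.71, adjusted p = 7.0e-06). The call was lost with an estimated correlation (adjusted p = 0.2), and without WT 3D replicate 5 the median was -1.34 and 17 members fell. CDH1, the gene of E-cadherin, fell by 3.01, CRB3 by 2.40 and CDH3 by 2.33. Of 23 FOXO and quiescence-associated genes 9 fell and 1 rose (11 fell and 2 rose over the list alone; median -0.34, adjusted p = 7.85e-04), with TXNIP at -2.58, CITED2 at -1.29 and TRIB2 at 1.63. Under median scaling the median of this list was 0.25, while the list was still shifted downward relative to other genes (adjusted p = 0.0143), and CITED2 did not pass (-0.70, adjusted p = 0.178).

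In 3D, 2441 genes differed between the cell lines, 1267 higher and 1174 lower in ErbB2* cells, and 739 by at least 2-fold. The count without WT 3D replicate 5 was 3038, 1500 higher and 1538 lower, with 2122 genes in common. Of those 3038 genes, 634 differed by at least 2-fold. Median scaling gave 1141 higher and 141 lower genes.

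The effect of culture was then read within each cell line, beginning with WT cells. HSD17B2, which encodes an enzyme that oxidises estradiol and testosterone, was 47.9-fold higher in 3D than in 2D (log2 signal 12.1 ± 0.135, SD, n = 5, against 6.48 ± 0.421, SD, n = 6). The AP-1 subunit gene FOSB was 30.8-fold higher, the pyruvate dehydrogenase kinase gene PDK4 was higher by a log2 change of 4.46, and the tetraspanin gene TSPAN7 was 20.2-fold higher. The actin regulator MTSS1, below background on most WT 2D arrays, was at least 19.2-fold higher. The actin-binding protein gene TAGLN, the secreted hormone gene STC1 and the keratin gene KRT80 were below background on most WT 3D arrays and at least 13.0-fold, at least 10.5-fold and at least 11.4-fold lower than in 2D, and SRGN was lower by a log2 change of -3.58 (SE 0.265, adjusted p = 4.94e-10). SUSD2 was below background on every WT 3D array and at least 8.69-fold lower than in 2D. Other probes of TAGLN (-1.76) and KRT80 (-1.17) moved the same way by less. By the same rule of choice, every 3D array lay beyond every 2D array for these 10 genes.

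Cell cycle genes fell in WT cells in 3D. Of 44 proliferation genes 37 fell and none rose (39 fell over the list alone; median -0.70, adjusted p = 2.68e-15). The ribonucleotide reductase gene RRM2 changed by -2.10, CDCA8 by -1.89 and the spindle gene TPX2 by -1.48. Without WT 3D replicate 5 RRM2 changed by -1.28 and CDCA8 by -1.23, and RRM2 did not pass with only the groups compared in the fit (-2.10, adjusted p = 0.0547). Of 23 FOXO and quiescence-associated genes 17 rose and 2 fell (the same over the list alone; median 1.07, adjusted p = 3.95e-11), among them PDK4, TXNIP (log2 change 2.67) and KLF9 (1.89). Of 20 NRF2 targets 11 rose and none fell (12 rose and 1 fell over the list alone; median 0.50, adjusted p = 1.76e-07), among them AKR1B10 (2.22), HMOX1 (1.38) and the cystine transporter SLC7A11, below background on most 2D arrays and at least 5.64-fold higher.

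In the same cells, of 21 ERK output genes 11 fell and 2 rose (13 fell and 2 rose over the list alone; median -0.42, adjusted p = 8.29e-04), with the phosphatase gene DUSP4 at -2.58, EPHA2 at -2.18 and IER3 at -1.99. Of 19 YAP and TEAD targets 11 fell and 2 rose (11 fell and 3 rose over the list alone; median -0.81, adjusted p = 0.00139), with F3 at -1.55, CCN2 at -1.52 and NUAK2 at -1.49. Of 13 BCL2 family genes 7 fell and none rose (8 fell and 1 rose over the list alone; median -0.67, adjusted p = 0.00647). These included the anti-apoptotic genes BCL2 (at least 1.83-fold lower, below background on most 3D arrays) and BCL2L1 (-0.93) and the mitophagy gene BNIP3L (-1.08); BCL2L1 did not pass under median scaling (log2 change -1.42, adjusted p = 0.0609).

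Mitochondrial and ribosomal protein genes shifted by less. Of 32 oxidative phosphorylation genes 12 rose and none fell (17 over the list alone; median 0.25, or -0.05 under median scaling; adjusted p = 8.18e-04). COX6A1 changed by 0.73, UQCRC1 by 0.48 and ATP5MC3 by 0.47. Of 36 ribosomal protein genes 5 rose and none fell (4 over the list alone; median 0.09, or -0.0011 under median scaling; adjusted p = 0.0289). RPL13 changed by 0.88, although another probe gave -0.01, RPL37 by 0.80 and RPS23 by 0.57. None of these 6 genes passed under median scaling, where ATP5MC3 was at -0.04. ATP5MC3 also did not pass without WT 3D replicate 2 (log2 change 0.40, adjusted p = 0.0561) or with only the groups compared in the fit (0.47, adjusted p = 0.0518), nor RPL13 with the mean over its probes (log2 change 0.43, adjusted p = 0.0682).

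In WT cells 3246 genes differed between the cultures, 1571 higher and 1675 lower in 3D, and 852 by at least 2-fold. When WT 3D replicate 5 was left out the count was 3692, 1871 higher and 1821 lower, with 2756 genes in common. At 2-fold or more, 361 genes were higher and 491 lower with that array, and 358 higher and 292 lower without it. The excess of lower genes thus depended on that array. Median scaling gave 202 higher and 1065 lower genes.

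In ErbB2* cells KANK4 was the gene with the highest fitted rise from 2D to 3D, a log2 change of 5.09 (signal 10.4 ± 0.211 against 5.28 ± 0.169, SD, n = 6 each, adjusted p = 4.93e-20). FOSB rose by a log2 change of 4.91, FABP4 29.6-fold and the stress-induced transcription factor gene ATF3 21.8-fold. POSTN, the gene of the matrix protein periostin, was below background on every ErbB2* 2D array and at least 22.1-fold higher in 3D. The probes that stand for FGL1, SERPINB3 and SERPINB4 were below background on every 3D array, at least 21.9-fold, at least 14.9-fold and at least 12.1-fold lower, although another FGL1 probe gave 0.42. IL1RL1 changed by -4.08. HP, the gene of the plasma protein haptoglobin, was below background on most 3D arrays and at least 14.0-fold lower. The choice of these 10 genes required that every 3D array lay beyond every 2D array.

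Cell cycle genes fell in ErbB2* cells too. Of 44 proliferation genes 35 fell and none rose (35 over the list alone; median -0.71, adjusted p = 1.41e-18), among them KIF20A (-1.21), BUB1 (-1.03) and CDK1 (-0.98). Inflammatory genes rose. Of 27 NF-kB and cytokine genes 17 rose and 5 fell (17 rose and 6 fell over the list alone; median 0.90, adjusted p = 3.13e-09), led by the interleukin genes IL1B (log2 change 4.18) and IL1A (3.33) and the NF-kB feedback inhibitor TNFAIP3 (4.03). Of 20 NRF2 targets 12 rose and none fell (14 over the list alone; median 0.38, adjusted p = 1.2e-08), among them HMOX1 (2.93), SLC7A11 (2.71) and TXNRD1 (1.23). Of 21 ERK output genes 10 rose and 3 fell (the same over the list alone; median 0.56, adjusted p = 0.00142), with EGR1 at 1.95, IER3 at 1.66 and the feedback inhibitor SPRY1 at -2.28. Of 22 p53 targets 5 rose and none fell (5 over the list alone; median 0.19, adjusted p = 0.00216). GADD45A rose by 1.93, TP53I3 by 1.37 and the cell cycle inhibitor gene CDKN1A by 1.16, while other probes gave 0.16 for TP53I3 and -0.04 for CDKN1A.

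Of 20 TGF-beta targets 12 rose and 1 fell in ErbB2* cells in 3D (13 rose and 1 fell over the list alone; median 0.80, adjusted p = 1.2e-08). The members that led the list were ID3 (log2 change 4.30), ID2 (3.63) and SMAD6 (2.66), which are also known as targets of bone morphogenetic protein signalling. Of 8 fibroblast and stromal markers 5 rose and none fell (5 over the list alone; median 0.91, adjusted p = 9.16e-06), among them POSTN, COL6A3 (2.37) and LUM, which was below background in 2D and at least 1.77-fold higher in 3D. Of 5 adipocyte markers 2 rose (median 0.21, adjusted p = 0.00647, and adjusted p = 0.0638 with an estimated correlation). Of 17 keratinocyte differentiation genes 6 fell and 2 rose (7 fell and 3 rose over the list alone; median -0.26, adjusted p = 0.00315), among them SERPINB3, SERPINB4 and the calprotectin subunit gene S100A9 (-3.93). That call was lost without the detection filter (adjusted p = 0.088).

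In ErbB2* cells 2454 genes differed between the cultures, 1133 higher and 1321 lower in 3D, and 530 by at least 2-fold. Without WT 3D replicate 5, which took part only through the shared estimate of spread, 3971 genes passed, including all 2454. Median scaling gave 317 higher and 585 lower genes, and CDK1 (-1.12, adjusted p = 0.0973), TXNRD1 (1.11, adjusted p = 0.0565) and TP53I3 (1.22, adjusted p = 0.0748) did not pass under it.

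**Figure D3:**
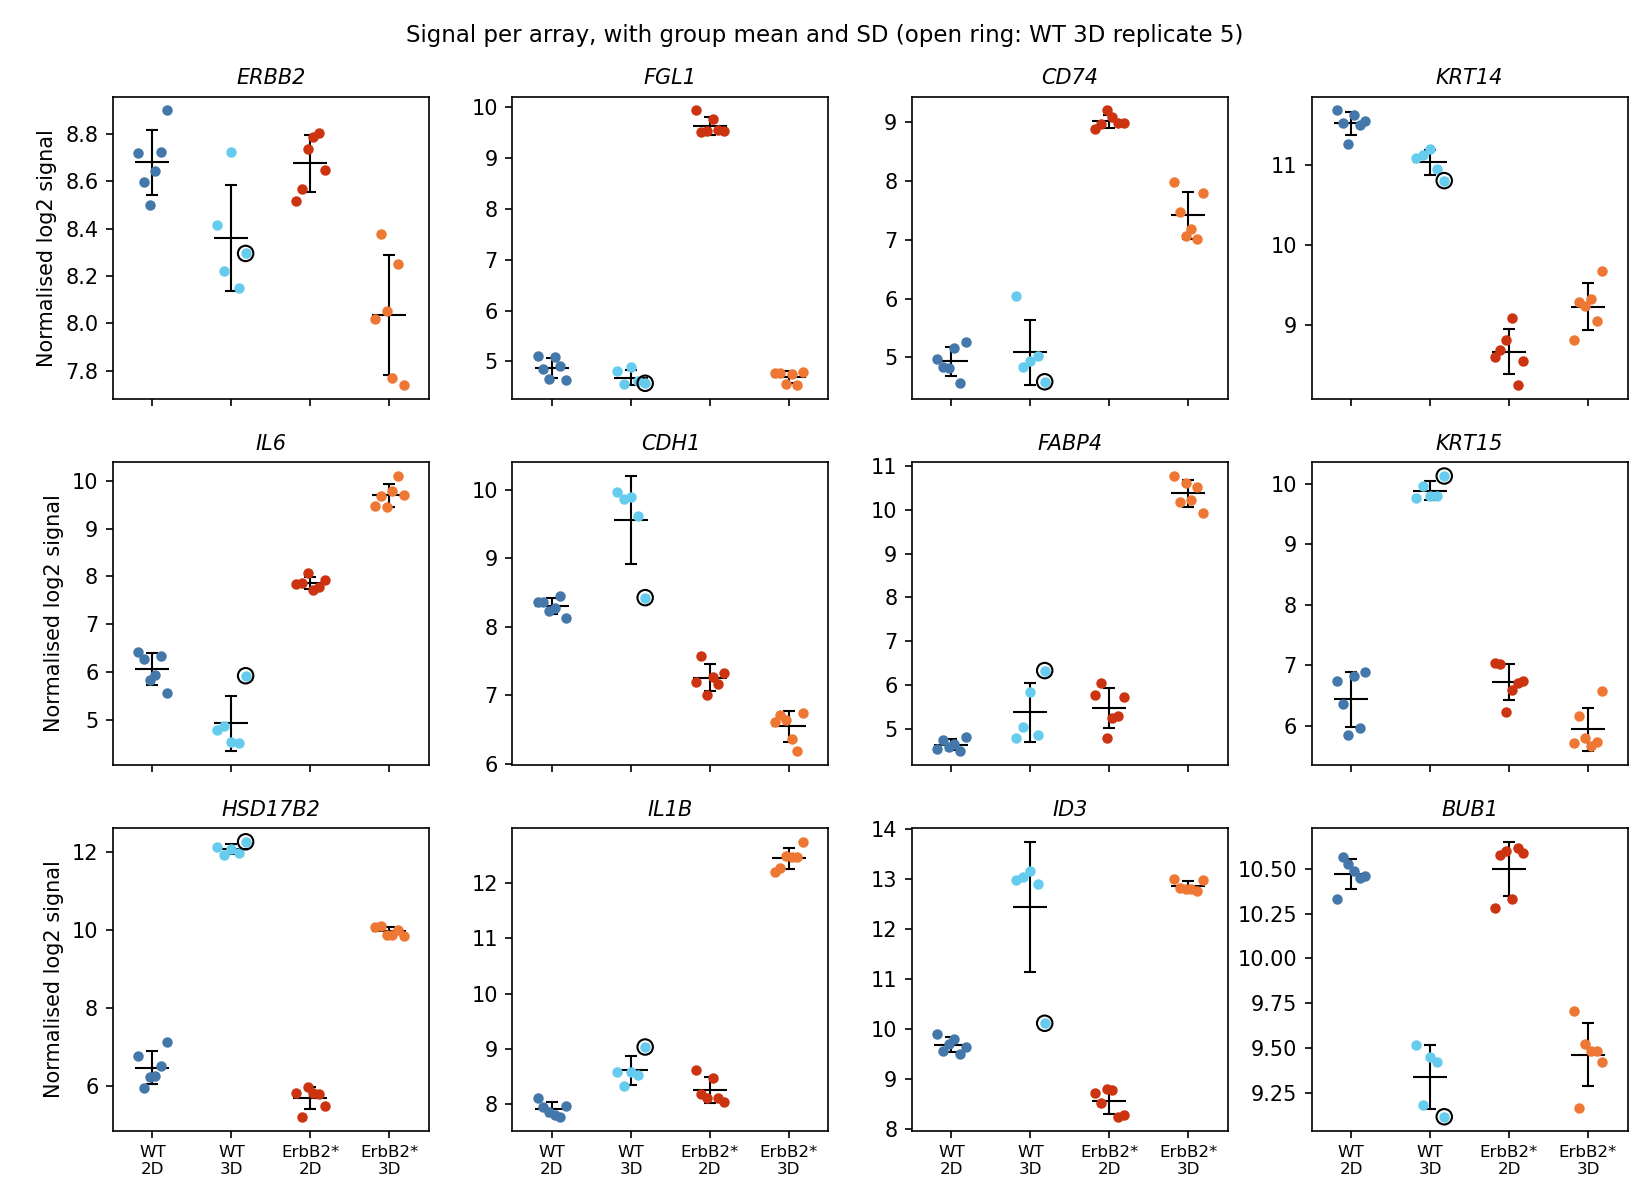
Normalised log2 signal (vertical axis) of 12 genes on each of the 23 arrays, by group, with the group mean (horizontal line) and SD (error bars); the open ring marks WT 3D replicate 5. FGL1 had its highest group mean in ErbB2* cells in 2D (9.63) and FABP4 in ErbB2* cells in 3D (10.4), while BUB1 had means of 10.5 in 2D and of 9.34 (WT) and 9.46 (ErbB2*) in 3D.

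The 4 groups let each effect be read on separate arrays. Across the 10954 genes, the difference of ErbB2* from WT cells in 2D and that in 3D were set against each other. They had a Pearson correlation of 0.248 (jackknife SE over arrays 0.121) and a Spearman correlation of 0.0883. Of the genes that passed in each, 351 were higher in both cultures, where independent lists would share 98.5, and 217 were lower in both, where independent lists would share 62.6. A further 146 genes moved in opposite directions, against 158.9 for independent lists. Without WT 3D replicate 5 the Pearson and Spearman correlations were 0.339 and 0.178, and 519, 369 and 276 genes were higher in both, lower in both and opposite, against 191.2, 161.0 and 353.1. The culture effects in WT and ErbB2* cells had a Pearson correlation of 0.360 (jackknife SE over arrays 0.0918) and a Spearman correlation of 0.289. There 496 genes rose in both lines, where independent lists would share 162.5, and 533 fell in both, where independent lists would share 202.0, while 183 went opposite ways against 362.7. With that array left out the correlations were 0.426 and 0.366, and the counts 782, 850 and 296, against 319.2, 349.4 and 669.7. These correlations are across genes, which are not independent replicates, and the compared effects share no arrays.

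Whether the culture effect differed between the cell lines was tested as an interaction. TXNIP rose by 2.67 from 2D to 3D in WT cells and fell by 1.37 in ErbB2* cells, an interaction of -4.04 (SE 0.215, adjusted p = 5.17e-12). KRT15 rose by 3.46 in WT cells and changed by -0.78 in ErbB2* cells (interaction -4.24). The probes for FGL1 (-4.74), SERPINB3 (-4.21) and SERPINB4 (-4.14) were below background on every array of the 3 groups other than ErbB2* cells in 2D, so these fitted interactions rest on levels that were not measured above background. In the other direction, SRGN fell in WT cells and changed by 0.69 in ErbB2* cells (adjusted p = 0.0553; interaction 4.27), and the tetraspanin gene TSPAN5 fell by 3.27 in WT cells and rose by 0.95 in ErbB2* cells (4.22). FABP4, below background on most or all WT arrays in each culture, had a fitted interaction of 4.15, POSTN, below background in ErbB2* cells in 2D, one of 4.11, and SCG5 one of 4.09. Another POSTN probe gave 1.65 and another FGL1 probe 0.48.

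Among the gene lists, ERK output had the smallest p of the interaction tests, with 11 of 21 members at a positive interaction and 1 at a negative one (13 and 1 over the list alone; median 0.98, adjusted p = 3.07e-08). TGF-beta targets followed (12 positive and 1 negative of 20; 13 and 1 over the list alone; median 1.18, adjusted p = 3.59e-07), then YAP and TEAD targets (8 positive and 1 negative of 19; 11 and 1 over the list alone; median 0.77, adjusted p = 3.07e-06). The interferon list (median 0.07, adjusted p = 0.638), the antigen presentation list (0.02, adjusted p = 0.839) and the proliferation list (-0.03, adjusted p = 0.988) did not pass. In all, 1649 genes had an interaction past the threshold, 737 positive and 912 negative, and 772 of them had an absolute difference of log2 fold changes of at least 1. Leaving out WT 3D replicate 5 gave a count of 2359, with 1616 genes in common. Median scaling gave 248 positive and 82 negative interactions.

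**Figure D4:**
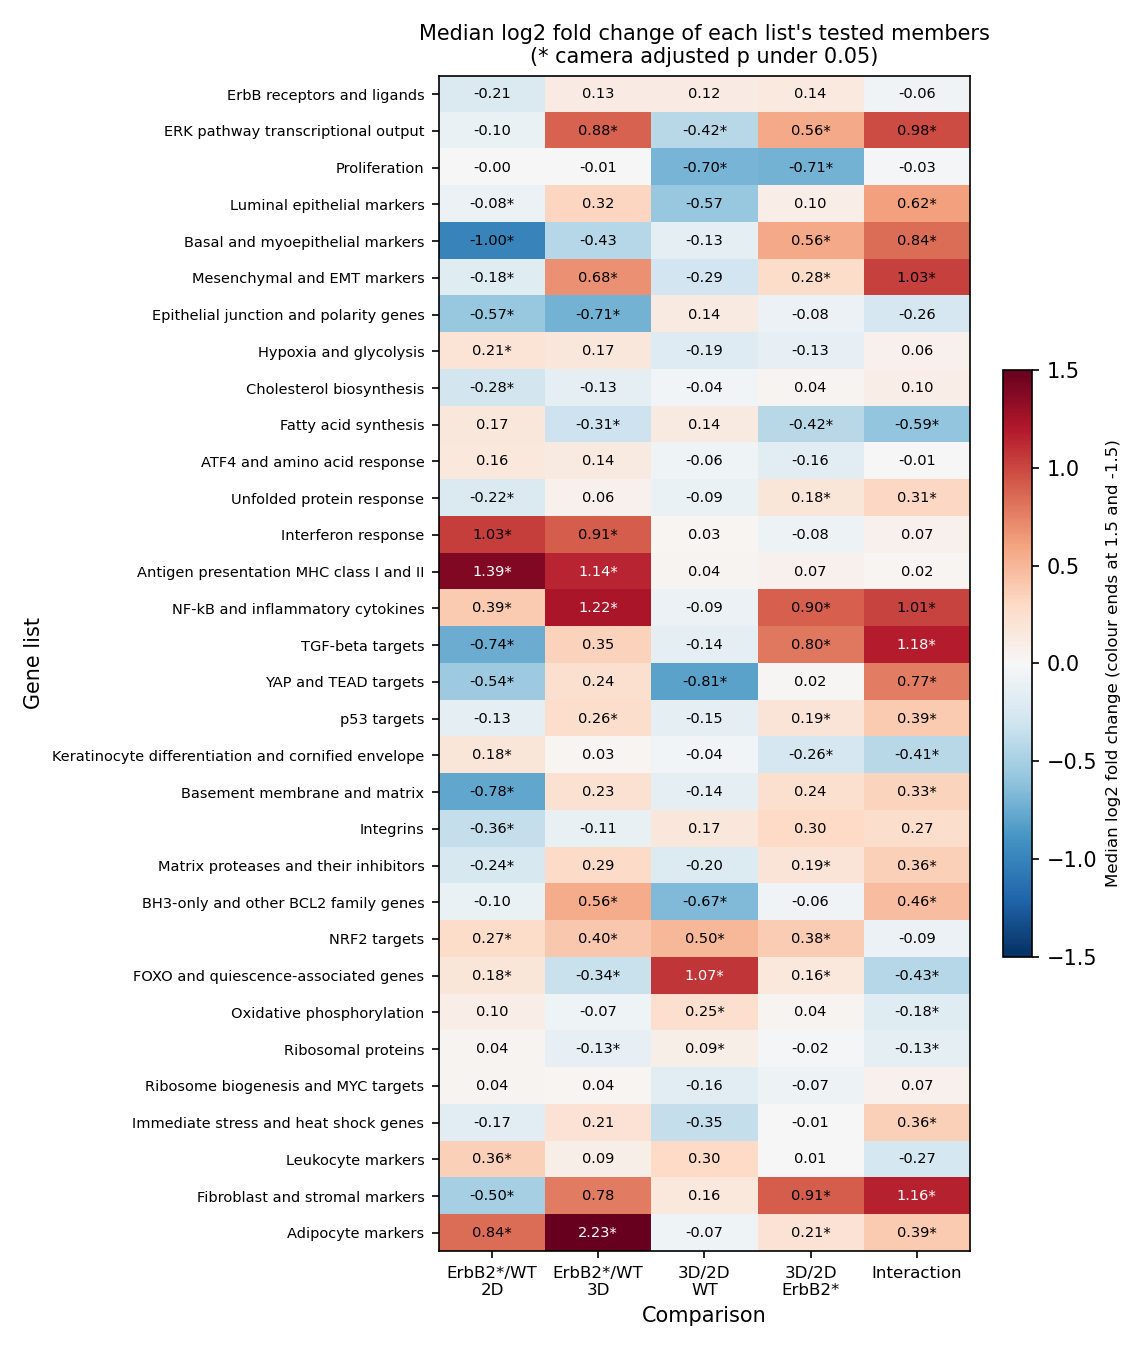
Median log2 fold change of the tested members of each of 32 gene lists (vertical axis) in the 5 comparisons (horizontal axis), coloured from blue (lower) to red (higher) with the value printed; an asterisk marks an adjusted p past the threshold. The interferon medians were 1.03 and 0.91 for ErbB2* against WT cells in 2D and 3D, and the proliferation medians were -0.70 and -0.71 for 3D against 2D in WT and ErbB2* cells; under median scaling the medians change sign for unfolded protein response (ErbB2* against WT, 2D), fatty acid synthesis, FOXO and ribosomal proteins (ErbB2* against WT, 3D), oxidative phosphorylation and ribosomal proteins (3D against 2D, WT) and oxidative phosphorylation (interaction).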

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

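The tests of explanations for WT 3D replicate 5, for the WT arrays in 2D and for the markers of other cell types were chosen only after the results were seen; the tests for outlying arrays, of the interaction, of probes without a gene name and of other splits of the arrays were planned. Among 20 measures of the arrays by group, 4 had an array far from the rest of its group, and each time it was WT 3D replicate 5. It had the lowest mean signal (150.6), the fewest detected probes (9329), a rank correlation of 0.503 between its scanner and deposited log2 columns and a mean correlation of 0.832 with its group on the scanner values. Of 100 named genes, 35 had an outlying array among WT cells in 3D (34 times replicate 5), 4 among WT cells in 2D, 5 among ErbB2* cells in 2D and 4 among ErbB2* cells in 3D. Chance gives such an array in about 5% of groups, 1 in 20.

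For WT 3D replicate 5, low signal accords with the 9329 detected probes, against at least 15080 elsewhere, and a scanner column that is not the source of the deposited log2 column accords with the rank correlation of 0.503, against 1.000 on other arrays. Its cell line field named ErbB2*, so its position between the mean of WT cells in 3D (0) and that of ErbB2* cells in 3D (1) was taken over 3038 genes: 0.048 on the deposited values and 0.122 on the scanner values. Other WT arrays reached 0.034 on each, and the lowest ErbB2* arrays were at 0.933 and 0.945. The genes were chosen for separating those other arrays, which narrows their ranges. For the deposited column the position argues against a sample of ErbB2* cells. For the scanner column this stays undecided, since by rank it matched the deposited column of ErbB2* 3D replicate 1 best. Of the same genes, 84.6% were nearer WT on its deposited values and 59.6% on its scanner values, against at least 93.1% on other WT arrays and at most 15.31% on ErbB2* arrays. On the other arrays the deposited columns kept the ranks of the scanner columns. The deposited column of replicate 5 correlated with its group at 0.994, against 0.991 to 0.995 for the other arrays. These values argue against low signal alone as the cause of the 0.503. Low signal stays open for the few detected probes, and a column from another hybridisation for the rank correlation. No biological explanation was tested.

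The 6 WT arrays in 2D fell into 2 sets, replicates 1, 5 and 6 and replicates 2, 3 and 4. Deviations from the group mean correlated between 0.118 and 0.240 within the sets and between -0.536 and -0.382 across them, while the highest value within any other group was 0.075. Mean signal separated the sets (at most 372.5 in replicates 2, 3 and 4 and at least 384.2 in the others), which accords with a difference in signal, although 1 in 10 random splits would separate them and detected probes overlapped. A culture state nearer to 3D in 1 set could not be decided. The difference between the sets had a correlation of 0.143 with the culture effect in ErbB2* cells. The whole culture effect in WT cells reached only 0.360 with it, so a shift toward 3D need not give a high value. Splits of the ErbB2* arrays in 2D reached an absolute 0.177, but with the culture effect in WT cells. An array batch cannot be told apart from other causes of the 0.118 or more within the sets, because no slide is given in the sources used here, and no biological explanation was tested.

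Adipocyte markers were higher in ErbB2* than in WT cells in both cultures, leukocyte markers in 2D (a call lost with an estimated correlation), and fibroblast markers rose in ErbB2* cells from 2D to 3D, which RNA of such cells could bring about. Of 12 ErbB2* arrays, 0 had a detected probe of the adipocyte genes ADIPOQ or PLIN1, 0 of the leukocyte genes PTPRC, TYROBP or ITGAM, and 1 of the collagen genes COL1A2 or COL3A1, all of them chosen after their values were seen. Cells of these types carry those transcripts in abundance. Because the genes were chosen after their values were seen, their absence cannot decide against adipocyte RNA, leukocyte RNA or fibroblast RNA. Other listed members were detected, such as COL1A1 on 1 ErbB2* array in 2D and 3 in 3D (WT: 1 and 4). LUM was detected on all 6 ErbB2* arrays in 3D. The leukocyte genes CD14, CD68 and LCP1 and the fibroblast genes DCN and COL6A3 were detected on every array of both lines. Other listed genes belong to the mammary line itself, such as LEP and PPARG of the adipocyte list, detected on every WT array. A hypothesis is that the ErbB2* cells themselves expressed the markers that rose, while cross-hybridisation of single probes was not tested.

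The interaction was tested directly, and the fitted culture effect differed between the cell lines past the threshold for 1649 genes. Of these, 318 were also called under median scaling, and the threshold allows a share of false calls. The named differences were -4.74 for FGL1, -4.24 for KRT15, -4.21 for SERPINB3, -4.14 for SERPINB4, -4.04 for TXNIP, 4.27 for SRGN, 4.22 for TSPAN5, 4.15 for FABP4, 4.11 for POSTN (3.46 without WT 3D replicate 5) and 4.09 for SCG5. The probes for FGL1, SERPINB3 and SERPINB4 were below background on every array of 3 groups, those for FABP4 in WT cells on every 2D and most 3D arrays and POSTN in ErbB2* cells in 2D, so the size of these 5 fitted differences was not measured. Median interactions of the lists that passed were 0.98 for ERK output, 1.18 for TGF-beta targets, 0.77 for YAP and TEAD targets, 1.03 for mesenchymal and EMT markers, 1.01 for NF-kB genes, -0.43 for FOXO genes, -0.41 for keratinocyte genes, 0.62 for luminal markers, 0.84 for basal markers and 0.39 for adipocyte markers. They were 0.39 for p53 targets, 0.36 for matrix proteases, 1.16 for fibroblast markers, -0.59 for fatty acid synthesis, 0.31 for the unfolded protein response, 0.36 for heat shock genes, 0.46 for BCL2 family genes, -0.13 for ribosomal proteins, -0.18 for oxidative phosphorylation and 0.33 for basement membrane genes. With an estimated correlation the call was lost for basement membrane (adjusted p = 0.311), oxidative phosphorylation (adjusted p = 0.167) and heat shock genes (adjusted p = 0.245). Median scaling ended the call for fatty acid synthesis (adjusted p = 0.138), BCL2 family genes (adjusted p = 0.137), heat shock genes (adjusted p = 0.119), ribosomal proteins (adjusted p = 0.0674) and oxidative phosphorylation (adjusted p = 0.356, median 0.0086). Without WT 3D replicate 5 it was lost for oxidative phosphorylation (adjusted p = 0.185) and heat shock genes (adjusted p = 0.0759), while the junction list passed (median -0.90, adjusted p = 6.68e-05).

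Of 3077 probes above background with no gene name in the annotation, 134 passed the threshold for ErbB2* against WT cells in 2D, 280 in 3D, 385 for culture in WT cells, 295 for culture in ErbB2* cells and 157 for the interaction.

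Among 100 splits of the arrays for each comparison, 1, the real one, gave as many genes, so each count depended on the labelled groups. Splits that mix the groups carry the group difference into the spread, which lowers their counts. Replicates may also be technical, so the splits cannot exclude chance differences between single cultures. The real counts and the highest of the other splits were 1436 and 223 for ErbB2* against WT in 2D, 2441 and 1477 in 3D, 3246 and 2049 for culture in WT cells, 2454 and 526 in ErbB2* cells, and 1649 and 103 for the interaction. At 2-fold or more they were 421 and 101, 739 and 475, 852 and 583, 530 and 167, and 772 and 88 in the same order.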

How the results depend on the processing

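All alternatives were planned except the tests on the 22 arrays other than WT 3D replicate 5, which were chosen after seeing the data. Comparisons are given in the order ErbB2* against WT in 2D and in 3D, 3D against 2D in WT and in ErbB2* cells, and interaction. The 40 list results counted here had the smallest camera p in each comparison, out of 77 list tests past the threshold. The other list tests are not in this count, and some lost their call under median scaling or without WT 3D replicate 5. Of the 40, 37 kept their call and the direction of the camera test, which is relative to other genes, in every alternative run. Under median scaling the medians of 3 of them changed sign (FOXO genes in ErbB2* against WT cells in 3D to 0.25, oxidative phosphorylation and ribosomal proteins in WT cells from 2D to 3D to -0.05 and -0.0011). Of 138 gene results 119 kept direction and call; the stricter detection filter tested 115 of these gene results. Among these 40, junction genes lost their call with an estimated correlation (camera adjusted p = 0.167 in 2D and 0.2 in 3D). Their lowest camera adjusted p over the alternatives was 2.77e-09 in 2D and 7.97e-15 in 3D. Keratinocyte genes in ErbB2* cells lost theirs without the detection filter (camera adjusted p = 0.088). Signal over background limits faint genes: adding an offset or leaving the background in shrinks their fold changes by construction, while the cause of other changes was not tested.

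At 2-fold or more, no background correction gave 190, 310, 337, 227 and 344 genes, normexp with an offset of 50 gave 228, 369, 439, 276 and 438, the deposited log2 values gave 126, 188, 194, 169 and 220, and those of the 22 other arrays gave 126, 194, 195, 169 and 219. Median scaling gave 634, 1282, 1267, 902 and 330 genes past the threshold, of which 604, 1075, 1131, 866 and 318 were also called under quantile normalisation, in the same direction; for the interaction, 318 had a difference of at least 1. Past the threshold the deposited log2 values gave 2736 (ErbB2* against WT, 2D), 4088 (culture, ErbB2*) and 2752 (interaction), those of the 22 other arrays 2698, 4050 and 2570, and array weights 2373, 4178 and 2570, with a weight of 0.029 for WT 3D replicate 5. Repeating the background and quantile steps on the 22 other arrays gave 2542 and 3970 for ErbB2* against WT in 2D and for culture in ErbB2* cells. With only the groups compared in the fit the counts were 2203, 1545, 1797 and 3987. Leaving out 1 array at a time gave 1214 (without WT 2D replicate 2) to 2543 (without WT 3D replicate 5) genes for ErbB2* against WT in 2D and 2176 (without ErbB2* 2D replicate 1) to 3971 (without WT 3D replicate 5) for culture in ErbB2* cells. The other comparisons gave 2073 to 3038, 2772 to 3692 and 1386 to 2359, list tests past the threshold 74 to 79, and the correlations of effects 0.218 to 0.339 and 0.335 to 0.426.

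ERBB2 for ErbB2* against WT in 2D was at -0.0044, at 0.22 under median scaling and between -0.041 (without WT 2D replicate 3) and 0.039 (without WT 2D replicate 6) with 1 array left out (adjusted p from 0.786 to 0.997 over the alternatives). In 3D it was at -0.32, at 0.23 under median scaling, and passed with the deposited log2 values (-0.22, adjusted p = 0.0216) and with array weights (-0.36, adjusted p = 0.0207). For culture in WT cells ERBB2 was at -0.32 and passed with no background correction (-0.25, adjusted p = 0.0421), normexp with an offset of 50 (-0.27, adjusted p = 0.047), the deposited log2 values (-0.20, adjusted p = 0.0255) and the stricter detection filter (-0.32, adjusted p = 0.0439); adjusted p ranged from 0.0158 to 0.125 over the alternatives. With the deposited values of the 22 other arrays it also passed in both comparisons (-0.21, adjusted p = 0.0447 in 3D and -0.21, adjusted p = 0.0361 for culture), and in 3D with the steps repeated on those arrays (-0.34, adjusted p = 0.049). ATP5MC3 for culture in WT cells was at 0.47 and at -0.043 under median scaling. The cause was not tested.

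Replicate numbers were tried as a block. Equal numbers in different groups did not pair the arrays: 30 same-number pairs had correlations of deviations between -0.187 and 0.172, and 3 of 22 arrays had their best match at their own number. The block gave 1318, 2221, 2957, 2309 and 1444 genes and changed no call among the named genes and lists. A slide block was not run, because no slide is given in the sources used here.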

Other observations

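No tests in this part were chosen after the results were seen. In ErbB2* against WT cells in 2D, further lists fixed beforehand passed, here given as counts. Of 21 basement membrane genes 11 fell and 3 rose (median -0.78, adjusted p = 7.79e-06), of 24 matrix proteases and inhibitors 8 fell and 1 rose (median -0.24, adjusted p = 1.6e-04), and of 12 integrins 6 fell and 2 rose (median -0.36, adjusted p = 0.0171, and adjusted p = 0.163 with an estimated correlation). Of 17 keratinocyte differentiation genes 6 rose and 1 fell (median 0.18, adjusted p = 1.98e-04), and of 28 hypoxia genes 8 rose and 1 fell (median 0.21, adjusted p = 0.00163). Of 19 cholesterol synthesis genes 5 fell and 1 rose (median -0.28, adjusted p = 0.0106, and adjusted p = 0.0892 under median scaling). Of 17 unfolded protein response genes 4 fell and none rose (median -0.22; 0.04 under median scaling, where the call was lost with adjusted p = 0.162).

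In 3D, of 14 fatty acid synthesis genes 7 fell and none rose in ErbB2* against WT cells (median -0.31, adjusted p = 0.00314; median 0.21 under median scaling, where the call was lost with adjusted p = 0.142). Of 13 BCL2 family genes 7 rose and 1 fell (median 0.56, adjusted p = 0.0101, and adjusted p = 0.114 under median scaling). Of 18 mesenchymal and EMT markers 8 rose and 2 fell (median 0.68, adjusted p = 0.00276; adjusted p = 0.147 with an estimated correlation and 0.0602 under median scaling). From 2D to 3D in ErbB2* cells, 6 of 13 basal and myoepithelial markers rose and 2 fell (median 0.56, adjusted p = 0.0224, and adjusted p = 0.201 under median scaling). The lists of ErbB receptors and ligands, of ATF4 targets and of ribosome biogenesis and MYC targets passed in none of the 5 comparisons.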
